A study of Caenorhabditis elegans with 2 samples.

How the data were processed

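RNA of whole L4 animals was compared between 1 control library (strain SJ4100, with the hsp-6 promoter reporter) and 1 library of animals with neuronal fzo-1 RNAi (strain CLP830), grouped by the strain and genotype in the labels. Per the labels, the growth temperature was 20 degrees Celsius, while the growth protocol gives maintenance at 25, and which holds for these animals is not settled here. Per the labels' protocols, libraries were made with a strand-specific kit for single-end or paired-end sequencing. Per the submitters' processing notes, TopHat, Cufflinks and the build WBcel235 were used; their versions, the annotation and whether values were counted by strand are not given in the sources used here, so overlapping and antisense genes are less certain.

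The deposited table gives, per the file headers, 1 value per gene and library. These are taken as FPKM, fragments scaled to transcript length and library size, from the size of the deposited values and the submitters' processing notes. The column names spell zcIs13 and fzo-1 slightly differently from the labels, and each column was matched to the library whose title it fits. The authors' deposited ratio and log2 ratio divide RNAi by control, and the deposited p-value and q-value come from a test that is not named in the sources used here. The deposited list of differing genes and enrichment tables were read as they stand. A value of 0.0001 FPKM stands for no expression in the deposited table: 26686 genes had it or less in both libraries, 827 in the RNAi library alone and 1032 in the control library alone, and no fold was computed for these.

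For the other genes log2((RNAi + 1)/(control + 1)) was computed, a scale that understates the difference of low genes. Genes with a mean of at least 1 FPKM and a value above the placeholder in both libraries were compared, and a gene was counted at 2-fold or more on that scale. Folds printed for single genes are plain ratios of FPKM. There are no replicates, so no test was run. The gene names or name patterns of the 48 lists and the limits were fixed before the data were examined, while the matching of names and the reading of a symbol, described below, were not. Each list's median was placed among the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression, and a list stands apart below percentile 2.5 or above 97.5, a description of these libraries and not a p-value. Genes named are fzo-1, hsp-6, hsp-60 and unc-119, the 12 genes with a symbol with the highest and the 12 with the lowest log2 ratio at a mean of at least 5 FPKM, and up to 4 members per list with the largest absolute log2 ratio; names outside these are members used for contrast or are said to be chosen later.

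List members were found by the symbols in the deposited table and, through gene identifiers, by current symbols of Ensembl release 115 for WBcel235. That matching, and reading a gene symbol as any name other than a sequence name, were settled after a first look at list values with the table's symbols alone; under that first matching the intestinal pathogen-response list was also lower, at percentile 2.20 with a median of -0.12. The identifiers of 43227 genes had an entry in the table of names. Lengths are those of the longest annotated transcript, known for 99.4% of genes compared, and coordinates come from the same annotation.

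Depth was read from the values: for 85.4% of 1893 genes below 0.3 FPKM in both libraries the ratio was 0.832 times a ratio of whole numbers up to 10, within a relative tolerance of 0.0001, against at most 4.12% for 20 shifted steps. The step gives the relative depth after the authors' scaling. The reads behind a gene were approximated from 135 genes at 1 read in each library, for transcripts of at least 400 nt, and gave the exact binomial intervals at the 95% level.

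The procedure was tested on 20 simulated tables of 12425 genes for this comparison, 200 of them changed. The size rule took 96.7% of genes changed 4-fold, 33.3% of those changed 2-fold and 0.0149% of unchanged genes. Simulated genes varied by counting and by a small assumed noise, with no trend on length. Without replicates the true noise is not known, so the shares taken by the size rule are not error rates for the real libraries. Of 1000 unshifted random lists 3.50% fell outside the band, and of 200 lists of 15 genes shifted by 0.2 on the log2 scale 81.5% lay above it. Alternatives were other pseudocounts (0.1 and 5), centring on the median, trimmed-mean scaling (30% of ratios and 5% of levels trimmed), other filters and fold limits, leaving out multicopy families, unmatched random lists and list means. Removing the trend on length, matching on length and the table's symbols alone were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.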

Results

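RNA was sequenced from whole Caenorhabditis elegans at the fourth larval stage (L4). There was 1 library of control animals carrying a reporter that joins the hsp-6 promoter to green fluorescent protein, and 1 library of animals with the same reporter plus an extrachromosomal transgene that makes double-stranded fzo-1 RNA from the unc-119 promoter, which is active in neurons. FZO-1 is the worm mitofusin, which fuses mitochondrial outer membranes. The comparison asks how the RNA of the whole animal differs when fzo-1 is targeted by RNA interference in neurons. Per the genotypes in the labels the control animals carry no extrachromosomal transgene, so any effect of carrying one is part of the comparison. With 1 library per group no difference has a replicate check, so "higher" and "lower" describe these libraries and no p-value is given across genes. Of 46245 genes listed, 17700 were above the placeholder for no expression in both libraries, and 13379 with a mean of at least 1 FPKM were compared. From the steps of the low values, the RNAi library was about 1.202 times as deep as the control library, near 39000000 against 32400000 reads. Intervals given for single genes are exact 95% binomial intervals from these approximate reads and cover counting error only.

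The targeted gene fzo-1 (WBGene00001509, WBcel235 chromosome II, 5833328 to 5836203, minus strand, protein-coding) was not lower in the RNAi library. It stood at 42.5 FPKM against 35.6 FPKM in the control library, 1.195-fold higher, with a counting interval of 1.14 to 1.25. The value checks the label only in part, since reads from the double-stranded RNA of the transgene may map to the gene and neurons are a part of the animal. The endogenous hsp-6 gene (V, 4824124 to 4826760), which encodes the mitochondrial Hsp70 chaperone read out by the reporter, stood at 378 FPKM with RNAi and 380 FPKM in the control, a ratio of 0.993 with a counting interval of 0.978 to 1.01. The mitochondrial chaperonin gene hsp-60 (III, 1619742 to 1625803) was 1.36-fold lower, at 291 against 397 FPKM. The gene whose promoter drives the transgene, unc-119 (III, 10902641 to 10908935), stood at 14.3 against 16.53 FPKM.

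None of the 18 measured genes of the mitochondrial unfolded protein response differed by 2-fold. Their median log2 ratio was 0.07, at percentile 85.6 of random lists matched on expression, inside the central 95%. The member farthest from 0 was Y22D7AL.10, an hsp-10 type chaperonin gene, at 531 against 356 FPKM, while the protease genes ymel-1 and spg-7 had log2 ratios of -0.51 and -0.40. Of 16 genes of mitochondrial dynamics and mitophagy, 2 were at least 2-fold higher. These were dct-1, a mitophagy receptor, at 39.4 against 10.04 FPKM (3.93-fold, interval 3.48 to 4.44), and sqst-1, an autophagy receptor, at 44.5 against 19.9 FPKM. The fission genes fis-2 and fis-1 had log2 ratios of 0.64 and 0.54. The list median was 0.10 (percentile 88.0), and the mean of the list, in place of the median, lay at percentile 99.1. The 43 nuclear-encoded respiratory chain and ATP synthase genes had a median of 0.02 (percentile 76.8), with nduf-6 at 0.43, nuo-2 at 0.41 and nuo-5 at -0.33. The 12 genes encoded in mitochondrial DNA had a median of -0.12 (percentile 11.75), with ndfl-4 and nduo-6 at 1.05 and 1.004 (0.97 and 0.87 with the trend on length removed) and nduo-4 and ctc-1 at -0.42 and -0.40. Of these, ndfl-4 and nduo-6 meet at position 549 and each lies at a deposited locus of 2 genes. They may therefore not be separate differences. The 66 mitochondrial ribosomal protein genes, among them mrpl-50 at 0.48 and mrps-10 at 0.46, had a median of 0.07 (percentile 93.2).

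Across the 13379 genes, 284 were at least 2-fold higher and 242 at least 2-fold lower in the RNAi library. The highest log2 ratios among genes with a symbol belonged to the small heat shock gene hsp-16.41, at 87.2 against 2.95 FPKM (29.5-fold, interval 21.6 to 40.6), and the noncoding RNA gene tts-1, at 907 against 67.5 FPKM (13.4-fold, interval 12.65 to 14.3). They were followed by hsp-16.2 (11.6-fold), the pseudogene fbxa-193 (16.6-fold), the inducible chaperone gene hsp-70 (7.93-fold) and the nuclear hormone receptor gene nhr-17 (7.52-fold). The others of the 12 highest were dod-3 (6.29-fold), the P-type ATPase gene catp-3 (5.22-fold), the antimicrobial peptide gene cnc-4 (5.36-fold), the histone gene his-25 (5.65-fold), far-7 (5.50-fold) and mfb-1 (4.49-fold). In the deposited table the locus of hsp-70 holds 4 genes and those of nhr-17 and mfb-1 hold 3 each, so their values are less certain; 57 of the 197 genes picked for naming, not all of them given here, share a locus in this way.

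The lowest among genes with a symbol were scav-4, a scavenger receptor gene, at 1.38 against 9.49 FPKM (6.89-fold lower), and the lysozyme gene ilys-2, at 4.43 against 21.8 FPKM (4.93-fold lower). The S-adenosylmethionine synthetase gene sams-1 stood at 116 against 362 FPKM, 3.13-fold lower. The desaturase gene fat-5 was 3.29-fold lower, and the transcription factor genes nhr-31 and klf-3 were 3.35-fold and 3.82-fold lower. The others of the 12 lowest were nspe-1 (3.79-fold), ugt-63 (3.70-fold), drd-1 (3.51-fold), ugt-44 (3.47-fold), and the collagen genes col-62 (3.37-fold) and col-88 (3.13-fold). The deposited locus of fat-5 holds 3 genes and those of scav-4, klf-3 and nhr-31 hold 2 each. Some genes with sequence names alone, chosen after their values were seen, lay as far out. R09E10.13 was listed at 49.9 against 1.03 FPKM, and C08H9.15 at 6.16 against 42.7 FPKM.

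**Figure D1:**
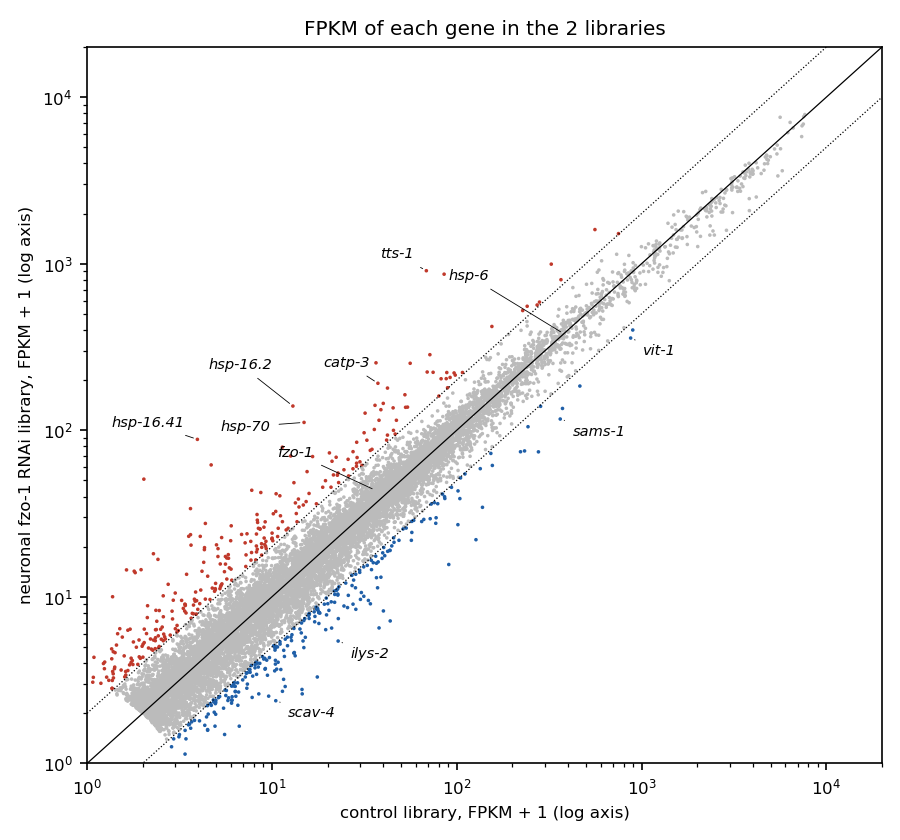
FPKM plus 1 of the 13379 genes compared, control library on the x axis and RNAi library on the y axis, both on log axes. Red points are the 284 genes at least 2-fold higher and blue points the 242 at least 2-fold lower, the solid line marks equal values and the dotted lines 2-fold. hsp-6 lies on the line of equal values and hsp-16.41 far above it.

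Both counts depended on the pseudocount: 423 higher and 491 lower with 0.1, and 133 higher and 72 lower with 5. A further 195 genes had at least 1 FPKM with RNAi and the placeholder in the control, and 152 the reverse, and no fold is given for them. The list of differing genes in the authors' deposited table held 508 genes, all with p of at most 0.05 and at least 2-fold in either direction, 292 higher and 216 lower. In the authors' deposited table, 166 of these 508 genes were at the placeholder in 1 library, 326 were among the genes compared here and 291 were at least 2-fold by the rule used here, so these counts are not of the same kind as 284 and 242. The authors' deposited table marked 31 genes as significant, 23 higher and 8 lower, with q up to 0.0469. The authors' deposited table gave hsp-70, hsp-16.2, tts-1, nhr-17, catp-3, sodh-1, icl-1, sams-1 and vit-1 a q of 0.0113, and fzo-1 a q of 0.999. The authors' deposited table also marked cnc-11 and dct-8, chosen after their values were seen and listed at 10.7 and 6.06 FPKM with RNAi and at the placeholder in the control. A test on the reads of 2 libraries compares those libraries, not the conditions.

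The log2 ratio went down with transcript length. Its median was 0.12 for the 1446 genes with transcripts under 500 nt, -0.10 for the 1881 genes from 2000 to 3000 nt, -0.27 for the 1155 genes from 3000 to 6000 nt and -0.59 for the 170 longer ones. Spearman's rho was -0.34 across 13304 genes, which are not independent replicates. For each list whose call differs, the percentile among random lists matched on length as well, an alternative chosen after the data were seen, is given beside the main one.

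**Figure D2:**
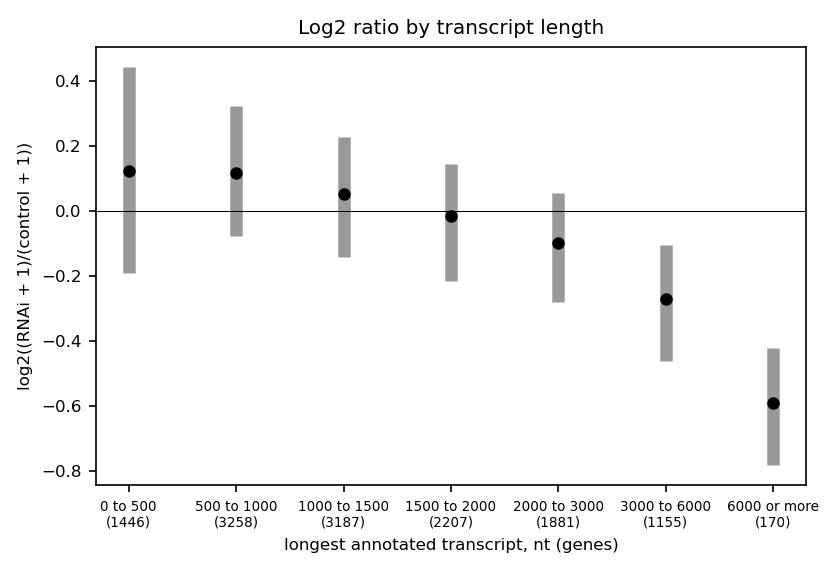
Log2 ratio of the RNAi over the control library by length of the longest annotated transcript. Points are medians, bars run from the lower to the upper quartile and the number of genes is in parentheses; the median goes from 0.12 under 500 nt to -0.59 at 6000 nt or more.

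Of the 48 gene lists, 21 lay outside the central 95% of random lists, 10 higher and 11 lower. For lists of independently drawn genes 2.4 would lie outside. Members of the real lists may vary together between any cultures, and some genes are in more than 1 list. The value of 2.4 is therefore not a chance expectation for these lists. Matched on length as well, 17 of these 21 were still outside on the same side.

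Of 12 measured cytosolic heat shock genes 4 were at least 2-fold higher: hsp-16.41, hsp-16.2, hsp-70 and hsp-16.11, the last at 4.36 against 0.780 FPKM and nearly identical to a neighbouring copy. The other 8, a group formed after the values were seen, had a median log2 ratio of 0.04 and hsp-43 at 0.52, and the Hsp70 and Hsp90 genes hsp-1 and daf-21, chosen after their values were seen, stood at -0.07 and 0.18. The list median of 0.15 was at percentile 97.2, inside the band, and at 98.7 when matched on length. It also went outside with a pseudocount of 5 (97.98), with no filter on the mean (99.99), by the mean of the list (100) and with the trend on length removed (99.8), and was at 91.4 with a mean of at least 5 FPKM. Of 16 genes activated by the insulin-pathway transcription factor DAF-16, 6 were at least 2-fold higher and 0 lower. Among them were dod-3, the alcohol dehydrogenase gene sodh-1 at 132 against 37.9 FPKM, the ferritin gene ftn-1 at 27.2 against 8.19 FPKM and the small heat shock gene hsp-12.6, 3.43-fold higher. The list median of 0.37 was at percentile 100. The 21 autophagy and lysosome genes had a median of 0.21 (percentile 99.5), with lgg-2 at 0.87, lgg-1 at 0.64 and epg-3 at -0.66; the mean of the list lay at percentile 97.2, inside the band. The 12 hypoxia and cysteine metabolism genes had a median of 0.23 (percentile 98.5), with sqrd-1 at 1.06 and egl-9 at 0.52; the mean of the list lay at percentile 94.1, and the median at 96.8 with the table's symbols alone. With the trend on length removed the median was 0.13 (percentile 90.2). The deposited locus of sqrd-1 holds 24 genes.

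The 17 endoplasmic reticulum stress genes had a median of -0.03 (percentile 32.98). Among them the stress kinase gene pek-1 had a log2 ratio of 0.94, the transcription factor gene xbp-1 0.45 and the chaperone gene hsp-4 0.23. With the trend on length removed the list median became 0.12 (percentile 99.1), a reversal of side. Matched on length the list lay at percentile 83.5, inside the band, so the 2 ways of handling length differ. The 23 oxidative stress and glutathione genes had a median of 0.13 (percentile 96.4), with gst-10 at -1.197 and gst-7 at 0.93. The 33 proteasome subunit genes had a median of 0.13 (percentile 98.8), with rpn-6.2 at 0.52 and rpn-12 at 0.45; the mean of the list lay at percentile 94.7, and the median at 97.4 of random lists not matched on expression.

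The lists of intestinal pathogen response and of intestinal genes both had a median below the band, -0.17 and -0.42, or -0.25 and -0.32 with the trend on length removed; the difference between them was not tested. Of 38 measured, 21 were below and 17 above 0, and 4 were at least 2-fold lower and 0 higher: ilys-2, drd-2, ilys-3 and C32H11.4, the last at 3.97 against 9.36 FPKM. With the trend on length removed drd-2 went from -1.08 to -0.55, while the list then held 5 genes at least 2-fold lower. The median of -0.17 was at percentile 0.37, and at 3.57 with no filter on the mean. The 88 C-type lectin genes had a median of -0.19 and the 12 lysozyme genes one of -0.30, at percentiles 0 and 0.92. Within these families clec-41 and clec-218 stood at -1.24 and -1.05, clec-190 at 1.57 and lys-5 at 0.88. Of 19 epidermal antimicrobial peptide genes, the 13 measured had a median of 0.05 (percentile 70.5), with cnc-4 at 2.28, nlp-31 at 0.69, cnc-3 at 0.69 and nlp-27 at -0.67. Genes at the placeholder in 1 library, such as cnc-11, have no ratio and enter no list median. The 22 fungus-induced protein genes had a median of 0.24 (percentile 99.8), with fipr-22 at 1.35; matched on length they lay at 79.6, with the trend on length removed at 93.3, with a mean of at least 5 FPKM at 93.2 and with no filter on the mean at 96.9. The 21 saposin-like genes, with spp-31 at 1.46, and the 11 pals genes, with pals-17 at -0.76, had medians of 0.01 and 0.02, at percentiles 59.6 and 54.7.

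Intestinal genes and the vitellogenin genes, which encode yolk proteins made in the intestine, were lower as lists. All 6 vitellogenin genes were below 0, with a median of -0.89 (percentile 0) and vit-1 at 357 against 872 FPKM, 2.44-fold lower. Their transcripts have a median of 4935 nt, where ratios were low in general, and with the trend on length removed their median was -0.50 (percentile 0.1) and vit-1 stood at -0.87 on the log2 scale. The median of -0.89 lay at percentile 0 of random lists matched on length. Of 19 intestinal genes 16 were below 0 and 2 at least 2-fold lower, the peptide transporter gene pept-1 at 42.2 against 101 FPKM and eps-8 at 20.8 against 47.7 FPKM, although the deposited locus of eps-8 holds 102 genes and with the trend on length removed eps-8 went from -1.16 to -0.97, leaving pept-1 alone past 2-fold lower. The intestinal GATA factor gene elt-2 stood at -0.98 and ftn-1, a member of this list too, at 1.62. The list median was -0.42 (percentile 0). Of 30 genes of fatty acid desaturation and oxidation 4 were at least 2-fold lower and 2 higher. The elongase gene elo-6, at a deposited locus of 6 genes, stood at 138 against 283 FPKM, the acyl-CoA synthetase gene acs-2 at 92.5 against 41.2 FPKM and the lipase gene lipl-2 at 5.43 against 2.002 FPKM. The median of -0.17 was at percentile 0.27, and with a mean of at least 5 FPKM at 2.69, inside the band; with the trend on length removed 3 genes were at least 2-fold lower. Of 50 UDP-glucuronosyltransferase genes, which conjugate small molecules, 6 were at least 2-fold lower and 1 higher, ugt-63, ugt-44 and ugt-48 at the low end and ugt-4 at 1.38. Their median was -0.23 (percentile 0.05).

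Other metabolic lists lay inside the band. The 21 genes of the tricarboxylic acid and glyoxylate cycles had a median of -0.11 (percentile 4.75), with sucl-1 at -0.45 and the glyoxylate cycle gene icl-1 at 554 against 240 FPKM, 2.31-fold higher. The 19 glycolysis genes, with aldo-1 at 0.32 and pyk-1 at -0.37, had a median of 0.09 (percentile 90.3, and 97.6 when matched on length). The 42 cytochrome P450 genes, with cyp-25A1 at -0.74, and the 37 glutathione S-transferase genes, with gst-1 at 0.84 and gst-36 at 0.83, had medians of -0.08 and 0.02, at percentiles 13.3 and 61.5.

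Of 21 neuronal genes 15 were below 0 and 0 passed 2-fold. The lowest were unc-31 at -0.93, rab-3 at -0.59, unc-17 at -0.58 and mec-12 at -0.57. With the trend on length removed they stood at -0.53, -0.60, -0.54 and -0.55, in the same order. The median of -0.19 was at percentile 2.66, inside the band, at 1.14 with a pseudocount of 5, at 0.39 with no filter on the mean and at 1.57 with random lists not matched on expression. Matched on length it was at 5.45, and with the trend on length removed the median was -0.10 (percentile 11.125). The deposited locus of unc-31 holds 6 genes. The 6 genes of serotonin synthesis, transport and reception had a median of -0.18 (percentile 16.6), with ser-4 at -0.40. The 13 Wnt ligand and secretion genes had a median of -0.15 (percentile 9.18), while the mean of the list lay at percentile 0.48; the beta-catenin gene bar-1 was 3.52-fold lower at 1.53 against 5.38 FPKM, and the receptor genes lin-18 and lin-17 stood at -0.95 and -0.89. The Wnt ligand genes egl-20 and mom-2, chosen after their values were seen, stood at 0.07 and 0.12. The neuropeptide families had medians of 0.04 for 30 FMRFamide-like, 0.06 for 68 neuropeptide-like and 0.08 for 22 insulin-like genes, at percentiles 64.3, 88.4 and 81.1. Their outer members were flp-34 at 1.25, nlp-48 at 1.37, ins-9 at -1.08 and daf-28 at -0.84. Of these nlp-48 and ins-9 were low and are uncertain. The first stood at 4.19 against 1.01 FPKM, at a deposited locus of 3 genes. The second stood at 0.490 against 2.16 FPKM, with a counting interval of 0.072 to 0.55 for the fold of RNAi over control. The 40 serpentine receptor genes, with srw-86 at 1.35, had a median of -0.01 (percentile 45.3). The value of srw-86 is uncertain too, at 2.03 against 0.187 FPKM with a counting interval of 3.39 to 115 for the fold. Of 21 muscle genes 15 were below 0, with a median of -0.13 (percentile 6.06, 22.1 when matched on length and 1.62 for the mean of the list). The lowest were the paramyosin gene unc-15 at -0.92 and the long genes unc-22, unc-89 and unc-54, of which unc-22 lies at a deposited locus of 22 genes. With the trend on length removed unc-15 stood at -0.71, unc-22 at -0.32, and unc-89 and unc-54 at -0.18 each.

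The collagen list and the molting list went in opposite directions. Of the collagen genes measured 83 were below and 21 above 0, 12 of them at least 2-fold lower and 0 higher, with a median of -0.39 (percentile 0). Of these col-149 stood at 134 against 372 FPKM and col-161 at 37.9 against 103 FPKM. Of 22 molting genes 17 were above 0, with a median of 0.33 (percentile 100) and bli-2, lpr-3, nekl-2 and sqt-1 at 1.18, 0.90, 0.78 and 0.75. Some collagens, such as bli-2 and sqt-1, are members of the molting list. The highest member of the collagen list stood at 0.68, so bli-2 and sqt-1 are not in that list or its counts. The opposite directions thus hold for the lists as drawn up, not for every collagen. The 48 abu and pqn genes, which encode prion-like proteins, had a median of -0.25 (percentile 0), with abu-8 at -1.49 and abu-11 at -1.23. The 23 hedgehog-like genes had a median of -0.16 (percentile 4.07, and 0.41 when matched on length), with grd-6 at -1.31 and wrt-10 at 1.07 (0.99 with the trend on length removed); the percentile was 0.24 with the trend on length removed, 2.37 with a pseudocount of 0.1 and 0.01 with a mean of at least 5 FPKM.

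Sperm genes lay higher as a list, and germline and oocyte genes did not. All 30 major sperm protein genes were above 0, with a median of 0.37 (percentile 100), or 0.21 with the trend on length removed (percentile 100), and msp-113 at 14.7 against 4.61 FPKM. They are near-identical copies, so single members are uncertain and the 30 may not be separate differences. The random lists behind the percentile do not allow for that. Of 21 other sperm genes 18 were above 0, with ssp-16 at 0.94; the median of 0.17 was at percentile 97.8, at 97.3 with a mean of at least 5 FPKM, at 87.6 when matched on length and at 93.7 with the trend on length removed. Of 24 germline genes 18 were below 0, with rnp-8 at -0.52 and glh-1 at -0.44; the median of -0.18 was at percentile 0.26, at 6.95 when matched on length and at 8.08 with the trend on length removed. The 20 oocyte and eggshell genes had a median of -0.07 (percentile 15.03), with moe-3 at 1.56, pqn-74 at -1.05 and cbd-1 at -0.60. The 31 genes of RNA interference and antiviral defence, with the Argonaute genes sago-2 at -0.84 and ppw-1 at -0.79, had a median of -0.13 (percentile 1.52); their transcripts have a median of 2983 nt, and matched on length they lay on the other side, at 68.5. With the trend on length removed they lay at 30.6, and with random lists not matched on expression at 2.62.

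Of 31 histone genes 7 were at least 2-fold higher and 0 lower, with a median of 0.51 (percentile 100); with the trend on length removed 4 were at least 2-fold higher. Besides his-25, his-11 stood at 16.46 against 4.104 FPKM and his-64 at 10.3 against 3.76 FPKM, as members of a family of near-identical copies. Such copies may not be separate differences, and the random lists do not allow for that. Of 91 F-box A genes and pseudogenes 63 were above and 28 below 0, with a median of 0.21 (percentile 100), and 5 were at least 2-fold higher and 0 lower. Besides fbxa-193, the gene fbxa-192 and the pseudogenes fbxa-129 and fbxa-21 stood at 2.06, 1.55 and 1.38. Of these fbxa-192, fbxa-193 and fbxa-129 lie close together on chromosome V, from 17640672 to 17656654, so they may not be separate differences. The 146 nuclear hormone receptor genes had a median of -0.01 (percentile 37.8), with nhr-17 at 2.80, nhr-114 at -1.34 and nhr-55 at -1.02. The 77 cytosolic ribosomal protein genes had a median of -0.09 (percentile 4.76), with rpl-41.1 at 0.91; the percentile was 0 when matched on length, 0.35 with the trend on length removed, 1.47 with no filter on the mean and 1.94 with random lists not matched on expression.

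**Figure D3:**
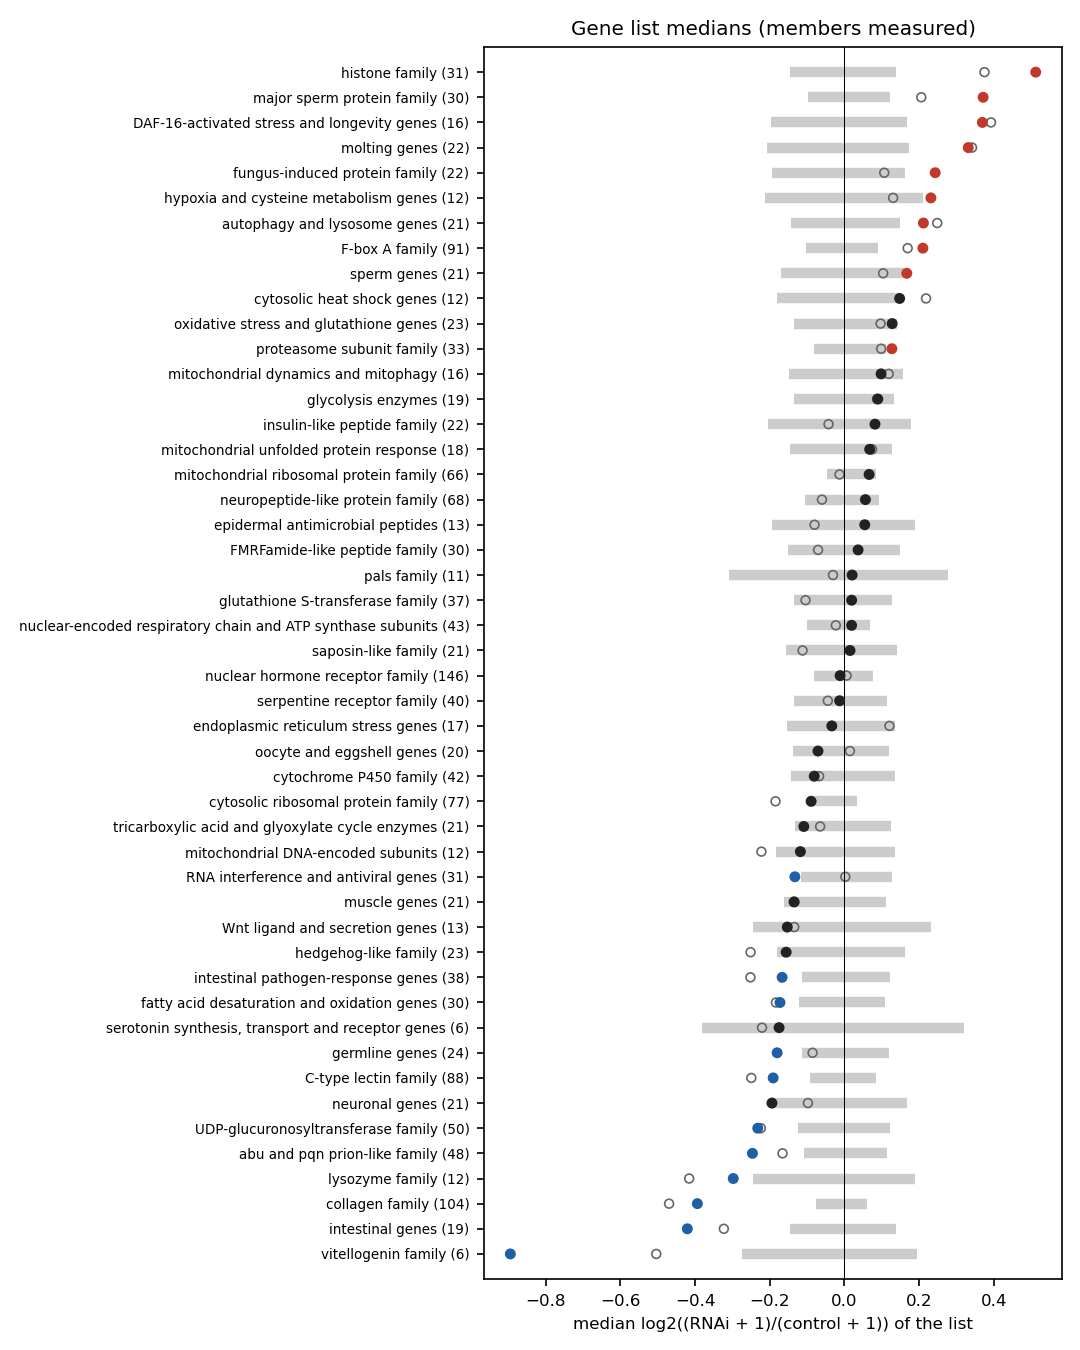
Median log2 ratio of each of the 48 gene lists, with the number of members measured in parentheses. Filled points are medians (red above, blue below and black inside the central 95% of 10000 random lists matched on expression, drawn as grey bars) and open circles are medians with the trend on transcript length removed, from -0.89 for the vitellogenin to 0.51 for the histone family.

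In the authors' deposited table of gene ontology terms 5 of 57 terms had a Benjamini value of at most 0.05. The first was the unfolded protein response of the endoplasmic reticulum, with 10 genes and a Benjamini value of 0.000160 in the authors' deposited table. In that term 4 abu genes were lower and hsp-70, hsp-16.41 and hsp-16.11 were among 6 higher genes of the authors' deposited table. The collagen trimer term had 12 genes in the authors' deposited table, all lower, and the intermediate filament term 5, all lower. The same 12 genes make up the term for structural constituents of the cuticle, also among the 5 terms. These terms were not examined here for the trend on transcript length. The authors' deposited table of 12 pathways had 0 with a Benjamini value of at most 0.05.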

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

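The settings on transcript length and the table's symbols were chosen after the data were seen, the others before. Of the 21 lists outside the band, 13 were on the same side under all 8 planned settings and 12 under all 11. Their number ranged from 19 to 23. The 2-fold counts moved with the pseudocount, from 284 higher to 133 with 5, and from 242 lower to 491 with 0.1 and 72 with 5. A 1.5-fold limit gave 814 and 1074, a 4-fold limit 38 and 12. Removing the trend on length put fzo-1 at 0.36 and hsp-6 at 0.090 on the log2 scale, outside their counting intervals. The mitochondrial dynamics and mitophagy list lay at percentile 99.1 by its mean, and the intestinal pathogen-response list at 3.57 with no filter on the mean. Removing the trend on length put the endoplasmic reticulum stress genes at 99.1, while matching on length put them at 83.5, inside the band. Matching on length put the RNA interference and antiviral genes at 68.5. The cause was not tested in any of these. Of 471 values of the other 43 lists, 432 were on the same side of the limits, 19 came inside and 20 went outside. Of 130 values of 26 other named genes 99 were within their counting interval, 31 were not or had none, and 0 changed sign. No paired analysis was possible because each group has 1 library. Depth limits short and low genes most, such as hsp-16.11, whose fold of 5.58 has a counting interval of 2.57 to 14.9.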

Other observations

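Chromosomes differed in their medians. The 1763 genes on X had a median log2 ratio of -0.10, and -0.09 with the trend on length removed, while those on chromosomes I to IV had medians from 0.01 to 0.03 and the 2496 on V one of -0.01. On X 37 genes were at least 2-fold higher and 49 lower, and on V 77 and 66.

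Of the tests below, the one of the trend within lists was set before its result was seen, and the others after. The lower ratio of longer transcripts may come from a lower yield of long RNA in the RNAi library. Such a yield would act within lists of related genes. Over 1560 members of 47 lists, each list's median log2 ratio and median log length were taken off. Spearman's rho was then -0.17 (95% bootstrap interval -0.22 to -0.12), between the limits set for and against a lower yield. Taking off the median length narrows the range of lengths, so a weaker rho than the -0.34 over all genes does not count against yield. Among the larger lists rho ran from -0.79 for the mitochondrial unfolded protein response to 0.22 for intestinal pathogen-response genes. The length correction in FPKM acts most near the fragment length, but rho was -0.34 for transcripts of at least 1500 nt and 0.04 under 500 nt, which argues against it as the cause. Whether yield or the makeup of the animals gives the rest cannot be told apart with 1 library per group.

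With the trend on length removed, the 4 heat shock genes at least 2-fold higher stayed at log2 ratios of 1.49 to 4.36, a fall of at most 0.12. These genes were picked for their high ratios, and a shift of that size could not bring any of them below 1. The values therefore show only that the trend is small at the lengths of these genes. Transcript length does not account for the place of the DAF-16-activated list, at percentile 99.97 when matched on length. A warmer culture could raise hsp-16 and hsp-70 genes, whose 4 measured members had a median log2 ratio of 3.16, while the other 8 members of the list had one of 0.037, which decides nothing. That explanation and an effect of neuronal fzo-1 RNAi cannot be told apart, because each group is 1 culture and the labels give 2 temperatures.

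For the lower vitellogenin genes, length as the whole cause is argued against by a percentile of 0 among lists matched on length. Length did take part of the vitellogenin difference. The collagen genes also lay at percentile 0, but that test could hardly come out for length. Their transcripts have a median of 1005.5 nt, where median ratios were above 0. With the trend on length removed the collagen median went from -0.39 to -0.47. Cultures harvested at different points of L4 may differ in vitellogenin, collagen, molting and sperm genes. The oocyte list, which would move with the vitellogenin genes, lay at percentile 46.4, between the limits set for and against, which decides nothing. Some oocyte genes were already expressed at harvest, with cbd-1 at 373 against 567 FPKM and moe-3 at 20.1 against 6.16 FPKM. A later switch-on therefore does not hold for all of them. Harvest time and neuronal fzo-1 RNAi cannot be told apart here, and the biological explanation stays untested. Nor can the carriage of a transgene, double-stranded RNA of any sequence or a difference between the strains be told apart from fzo-1 RNAi. This holds for every difference described, because the control animals carry no such transgene.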
